A study of Danio rerio with 7 samples.

How the data were processed

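Single-cell RNA sequencing was analysed from 7 zebrafish libraries of leukocytes sorted for eGFP under the coro1a promoter, which marks leukocytes. Per the labels' protocols, whole fish at 1 month were pooled from 15 fish, intestine and scale (epidermis) at 3 months from 3 fish, and the library labelled PBI-derived at 2 weeks from 120 heat-shocked fish. Tissues were dissociated in trypsin for 20 minutes (intestine and whole fish) or 30 minutes (epidermis), per the labels' protocols. Whole fish, intestine and scale each had 1 wild-type and 1 rag1 mutant library, so each group held 1 library and no comparison within a tissue had a replicate check.

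The deposited values were raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 on GRCz11, per the submitters' processing notes. Aligner settings and the annotation release were not given in the sources used here. The deposited matrices held 32534 features, of which 14 had identifiers outside Ensembl, among them EGFP, DsRedx, NTRO, trac and trdc. Every barcode had at least 500 UMIs. Gene names were taken from the files.

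The libraries held 93892 barcodes and between 69275555 and 155776467 UMIs each. Cells with fewer than 300 detected genes or more than 20% mitochondrial UMIs were left out, as were called doublets. Doublets were called within each library by comparing cells with simulated pairs, at 0.8% per 1000 barcodes, which marked 10195 barcodes. The filters on genes and mitochondrial UMIs removed 3631 barcodes, 10137 called doublets were left out of the rest (7.00% to 15.1% of a library), and 80124 cells were kept.

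Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen by their mean rank over libraries, and cells were clustered with the Leiden method at resolution 1 on 40 principal components and 20 nearest neighbours, with no integration of libraries (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1). The 64 clusters of the first round are written C with a number. Lymphoid clusters, with 49926 cells, were clustered again into 43 sub-clusters, written L with a number. A cluster was called "X-like" from marker lists set before the data were examined, when at least 3 markers of that class were detected in 10% of its cells at a log2 fold of at least 1 over the other clusters. It stayed unnamed when another class scored at least 0.75 times as high or had more markers among its top 10 genes. The names come from this clustering, and no annotation by the authors was used. Of 29 T-like markers 18 matched a feature, and cd3e, cd3g, trbc1 and trbc2 were among the 11 that did not. Those that matched included rag1, rag2, cd4-1, cd8a and cd28. Of 40 ILC/NK-like markers 37 matched. These classes were thus named from unequal panels, and the name ILC/NK-like does not exclude T cells.

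UMIs were summed per library and class. A class level is given in CPM (counts per 1000000 UMIs of that class) with an exact 95% Poisson interval, and a share of cells with an exact 95% binomial (Clopper-Pearson) interval. Both cover counting error only, and a count of 0 is given the limit of 3 counts. Shares were compared between genotypes by the mean log2 ratio over the 3 tissues, with 0.5 cells added, and an exact two-sided sign-flip permutation test. The smallest p this test allows with 3 pairs is 0.25. The labels do not say whether the intestine and scale libraries of a genotype came from the same 3 fish; if they did, the 3 pairs are not independent.

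Summed counts of ILC/NK-like, macrophage-like and neutrophil-like cells were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): quasi-likelihood F test, TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment over all genes tested. All 6 libraries entered 1 model with tissue and genotype, which left 2 residual degrees of freedom. The genotype contrast was rag1 mutant minus wild type over the 3 tissues, and the tissue contrast was scale minus intestine. Nothing in the labels says that the 3 pools of fish per genotype were raised apart, so the p-values measure only the spread between these libraries. That residual spread is the tissue-by-genotype difference, as no group had replicate pools from which to estimate a spread. A gene was called at an adjusted p under 0.05. On simulated counts with 200 changed genes per comparison, the genotype test of ILC/NK-like cells recovered 6.12% of 2-fold, 52% of 4-fold and 83.7% of 8-fold changes. The tissue test of these cells recovered 34% of 4-fold and 72% of 8-fold changes, and 11.9% of its 118 calls were false. The tissue test of macrophage-like cells recovered 49.0% of 4-fold changes, and 7.26% of its 124 calls were false.

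Gene lists set before the data were examined were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of a comparison: ILC1/NK subset, ILC2 subset, ILC3 subset, proliferation, V(D)J recombination and T-lineage, MHC class II presentation, interferon response, inflammatory cytokines and chemokines, antibacterial and granule, dissociation and heat stress, oxidative phosphorylation, ambient epithelial, and homeobox and tissue position. The homeobox list had fewer than 5 tested members in each comparison and was not tested.

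For the tissue comparisons, the genes named were the 12 called genes with the largest rise and the 12 with the largest fall among those with a named symbol that changed the same way in both genotypes, plus list members needed as examples. The PBI-derived library was compared with whole-fish wild type without a test. There the 12 largest log2 ratios of CPM plus 10 in each direction were named among genes with at least 50 UMIs in 1 of the libraries, and each list's median ratio was placed among 10000 random lists matched on mean expression.

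The alternatives chosen beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter except 1 count, doublets kept, no tissue block, 1 tissue pair left out, the 4 adult libraries alone, resolutions of 0.5 and 2, a minimum of 500 genes and 4000 variable genes. Further alternatives were added after seeing the data: leaving out each intestine library, counting 2 unnamed sub-clusters with T-cell markers as T-like, and testing the 12 tested gene lists without each tissue pair.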

Results

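The 7 libraries addressed which lymphoid cells remain in zebrafish that lack rag1, an enzyme of antigen receptor gene rearrangement that T and B cells need, and what innate lymphoid cells (ILCs) and NK cells look like in different tissues. After filtering, 7904 to 15844 cells were kept per library, with a median of 3293 to 7363.5 UMIs per cell. Each group was 1 library of pooled fish, so values within a tissue have no replicate and their intervals cover counting error only. All cells had passed a sort for coro1a-driven eGFP, so shares are shares of all kept sorted cells. These included cells not named as leukocytes, such as 5.82% epithelial-like and 1.81% stromal-like cells in mutant scale.

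The transcript of the targeted gene, rag1 (ENSDARG00000052122), remained in the mutants. It stood at 242 CPM over all kept cells of wild-type whole fish and 147 CPM in mutant whole fish. In scale it was 0 CPM in the wild type, which allows up to 0.0408 CPM, and 0.958 CPM in the mutant. In the intestine it was 0.0573 CPM in the library labelled wild type and 1.94 CPM in the library labelled rag1 mutant, and it was 77.8 CPM in the PBI-derived library. The mRNA therefore gave no check of the genotype labels.

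B-like and T-like cells made up smaller shares in the mutants of whole fish and scale, but in the intestine the labels ran the other way. B-like cells (cluster C40) made up 4.00% of wild-type whole-fish cells (95% interval 3.64 to 4.38) and 0.0252% of mutant cells. In scale they made up 0.581% of wild-type cells and 0 of 12281 mutant cells, which allows a share of up to 0.0244%. In the intestine, 0 of 10275 cells of the library labelled wild type were B-like, which allows up to 0.0292%, against 0.418% in the library labelled rag1 mutant. The log2 ratios of mutant over wild type were -7.14 in whole fish, -7.17 in scale and 6.44 in the intestine as labelled. Their mean was -2.62 (exact two-sided sign-flip permutation p = 0.5, n = 3 pairs), and -7.15 without the intestine pair. With doublets kept, the B-like share of mutant whole fish was 0.653% and the whole-fish ratio -2.80. Because T- and B-cell content went against the intestine labels, these libraries are called by their labels throughout.

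T-like cells followed the same order. In scale they were 4.76% of wild-type cells (4.39 to 5.15) and 0.326% of mutant cells, and in whole fish they were 24.0% and 15.8%. In the intestine the library labelled wild type held 0.389% T-like cells and the library labelled rag1 mutant 18.4%. The log2 ratios were -0.61 in whole fish, -3.85 in scale and 5.54 in the intestine as labelled, with a mean of 0.36 (exact sign-flip permutation p = 1, n = 3 pairs). Mutant scale and the intestine library labelled wild type held 40 T-like cells each. With other clusterings these counts were 0 to 14 and 3 to 15, and the ratios reached -10.19 in scale and 9.05 in the intestine. Without the intestine pair the mean was -2.23. Sub-clusters L2 and L3, which carried T-cell markers but stayed unnamed, would bring the T-like shares to 52.3% and 17.4% in whole fish, 30.4% and 1.97% in scale, and 0.409% and 18.4% in the intestine (wild type and mutant by label).

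The cells named T-like in mutant whole fish expressed recombination genes but little of the T-cell co-receptors. Of these cells, 77.3% fell in L6 and 18.9% in L32, whereas 51.1% of wild-type T-like cells fell in L12. L12 held 1362 of 11101 kept cells in wild-type whole fish and 13 of 15844 in the mutant, whereas L6 held 318 and 1931. The lower T-like share of mutant whole fish thus joined fewer L12 cells with more L6 cells. Within the class, cd4-1 was 110 CPM in wild type and 4.96 CPM in the mutant, cd8a was 44.5 and 2.17 CPM, and cd28, a co-stimulatory receptor, was 124 and 6.38 CPM. The transcript of foxp3b was 54.2 and 1.37 CPM. rag1 was 125 CPM in wild-type T-like cells and 485 CPM in mutant ones, rag2 was 30.6 and 90.1 CPM, and dntt, the polymerase that adds untemplated bases at receptor joints, was 9.60 and 73.1 CPM. The kinase gene lck stood at 456 and 512 CPM. The genes rag1, rag2, cd4-1, cd8a and cd28 were among the markers used to name T-like clusters. Their levels in this class are thus no independent evidence for its name. These levels leave out unnamed L2, with 3140 wild-type and 260 mutant whole-fish cells, where rag1 was 1229 and 1110 CPM, cd4-1 507 and 343 CPM and cd8a 318 and 299 CPM, so the contrast in rag1 depends on which sub-clusters are named.

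Antigen receptor transcripts over all kept cells ran in the direction of the cell shares in most families and tissues. Immunoglobulin light genes (13 features) were 101 CPM in wild-type whole fish and 0.267 CPM in the mutant, and 185 and 0.582 CPM in scale. V segments of the T-cell receptor alpha and delta loci (62 features) were 37.9 and 5.85 CPM in whole fish and 20.9 and 13 CPM in scale. In scale they differed less than the T-like shares (4.76% and 0.326%), with 1006 UMIs left in the mutant beside 40 T-like cells. Which cells held these UMIs was not tested. In the intestine, light genes were 0.472 CPM in the library labelled wild type and 7.01 CPM in the library labelled rag1 mutant, and the V segments were 11.3 and 27.9 CPM. Gamma V segments (13 features) followed in scale (7.43 and 0.337 CPM) and in the intestine as labelled (0.1 and 2.61 CPM) but not in whole fish (3.56 and 4.25 CPM). Immunoglobulin heavy V segments (40 features) followed in whole fish (113 and 17.8 CPM) and scale (229 and 7.33 CPM) but not in the intestine (17.2 and 17.1 CPM). The T-like cells of the latter library fell to 92.8% in L13, with cd8a at 292 CPM and cd28 at 228 CPM in that sub-cluster, and with no rag1 UMI among 1350 cells.

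**Figure D1:**
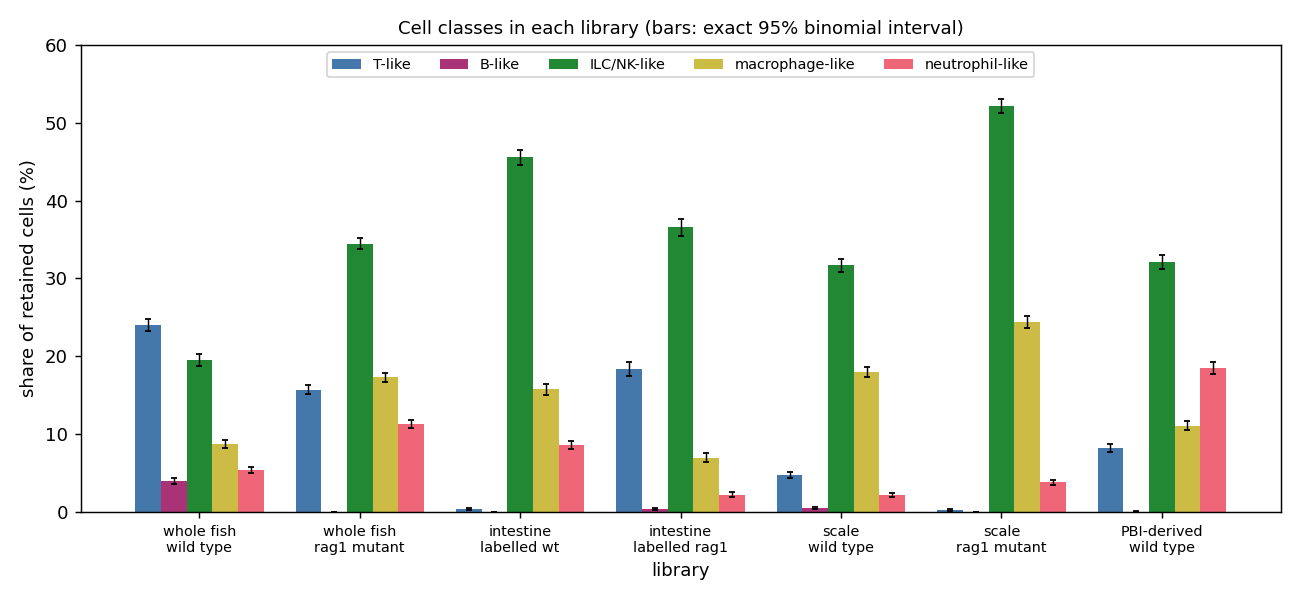
Share of kept cells (percent, linear axis from 0) in 5 named classes for each of the 7 libraries; bars are single libraries and error bars are exact 95% binomial intervals. T-like cells make up 24.0% of wild-type and 15.8% of mutant whole-fish cells, and ILC/NK-like cells are the largest of these classes in every library except wild-type whole fish.

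ILC/NK-like cells took a larger share in the mutants of whole fish and scale. They were 19.5% of wild-type whole-fish cells (18.8 to 20.3) and 34.5% of mutant cells (33.7 to 35.2), and 31.7% and 52.1% in scale. In the intestine they were 45.5% in the library labelled wild type and 36.6% in the library labelled rag1 mutant. The log2 ratios were 0.82, 0.72 and -0.32 for whole fish, scale and intestine as labelled, with a mean of 0.41 (exact sign-flip permutation p = 0.5, n = 3 pairs), 0.77 without the intestine pair and 0.05 at 0.5 times the resolution. The intestine ratio ranged over the alternatives from -1.34 at 0.5 times the resolution and -0.38 with 4000 variable genes to 0.014 at 2 times the resolution, 0.10 with doublets kept and 0.15 at 500 genes. A share moves with every other class, so these ratios say nothing of cell numbers. Unnamed cells, among them lymphoid sub-clusters, were 35.3% and 16.5% in whole fish and 32.8% and 8.76% in scale (wild type and mutant). In the intestine they were 26.6% and 31.4% (wild type and mutant by label). The largest sub-clusters of the class differed between libraries: L7 in both whole-fish libraries, L11 and L14 in the intestine library labelled wild type, L8 in the one labelled rag1 mutant, L5 in wild-type scale and L1 in mutant scale.

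The ILC1/NK, ILC2 and ILC3 genes peaked in different sub-clusters. L43 (179 cells) held the cytotoxic ILC1/NK genes at 29731 CPM, summed over 17 genes, followed by L10 at 5195 CPM, L27 at 4453 CPM and L9 at 4181 CPM. The ILC2 genes (8 measured) reached 13662 CPM in L21, of whose 1018 cells 633 and 307 came from the intestine libraries and 0 from scale, and 5074 CPM in L20, of whose 1025 cells 469 came from the PBI-derived library. The ILC3 genes reached 6717 CPM in L40 and 3518 CPM in L11, where 1297 of 1523 cells came from the intestine library labelled wild type. Most ILC/NK-like cells, 53.5% to 94.8% of a library, lay in sub-clusters led by none of these lists.

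Single genes of the 3 programmes differed between tissues in ILC/NK-like cells. The type 2 cytokine gene il13 was 861 and 711 CPM in the intestine libraries labelled wild type and rag1 mutant, 221 and 310 CPM in whole fish, and 41.8 and 30.1 CPM in scale. The NK-lysin gene nkl.1, which encodes an antimicrobial and cytolytic peptide, was 799 and 1128 CPM in whole fish, 135 and 71.9 CPM in the intestine libraries, and 205 and 401 CPM in scale. Other ILC1/NK genes ran otherwise, such as il2rb at 291 and 273 CPM in whole fish and 846 and 654 CPM in scale. The ILC3 cytokine genes il22 and il17a/f1 reached 88.9 and 84.0 CPM in mutant scale, against 16.4 and 4.86 CPM in wild-type scale, whereas il17a/f2 was 0.687 CPM in mutant and 22.1 CPM in wild-type scale. rorc, which encodes an ILC3 transcription factor, was 493 CPM in the intestine library labelled wild type and 186 CPM in the one labelled rag1 mutant, and 457 and 488 CPM in scale. Sub-clusters led by the ILC2 genes held 14.1% and 11.7% of ILC/NK-like cells in the intestine libraries but 1.04% and 0.781% in scale.

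**Figure D2:**
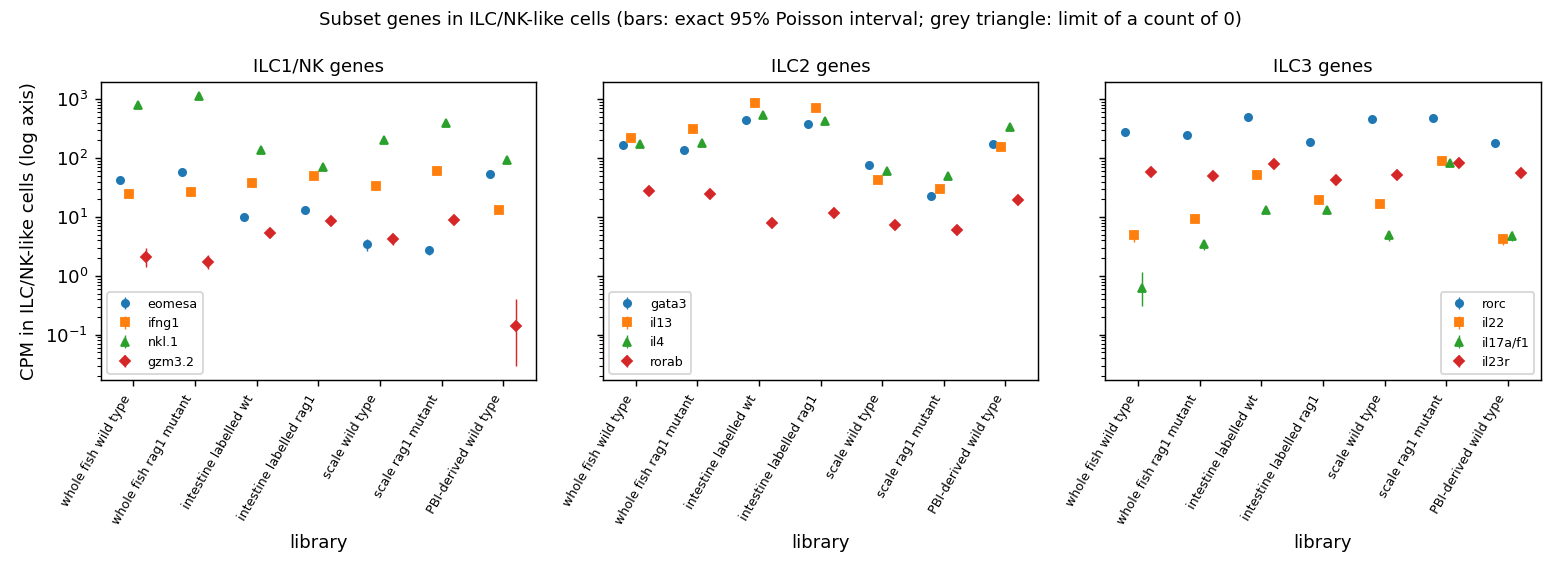
CPM (log axis) of 4 ILC1/NK, 4 ILC2 and 4 ILC3 genes in the ILC/NK-like cells of each library; points are single libraries and error bars are exact 95% Poisson intervals. The ILC2 gene il13 is highest in the intestine libraries (861 and 711 CPM) and lowest in scale (41.8 and 30.1 CPM).

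The genotype comparison asked which genes innate cells expressed differently in rag1 mutants over the 3 tissues. The clearest group was the interferon response. In ILC/NK-like cells, 17 of 19 tested members lay above 0 with a median log2 fold change of 1.23; in macrophage-like cells 19 of 19 did (median 1.46), and in neutrophil-like cells 17 of 17 (median 1.80). The camera test put the list up in each class (adjusted p = 6.6e-10, 7.3e-13 and 1.1e-11), a call that was lost with an estimated correlation (adjusted p = 0.532, 0.335 and 0.634 with an estimated correlation). Adjusted over the list alone, 8, 11 and 12 members rose; over all genes tested, 0 did in any class. The antiviral gene rsad2 went from 0.0630 to 11.6 CPM in ILC/NK-like cells of whole fish, from 1.07 to 16.7 CPM in scale and from 1.31 to 14.3 CPM in the intestine as labelled (log2 fold change 4.25 ± 0.63 SE, edgeR adjusted p = 0.974). The signal transducer stat1b had log2 fold changes of 2.87 ± 0.44, 2.18 ± 0.36 and 2.94 ± 0.35 (SE) in the 3 classes, with edgeR adjusted p of 0.974, 0.657 and 0.211. The immunoproteasome gene psmb9a was higher in the library labelled rag1 mutant in each tissue and class, with log2 fold changes of 1.39, 1.69 and 1.80.

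**Figure D3:**
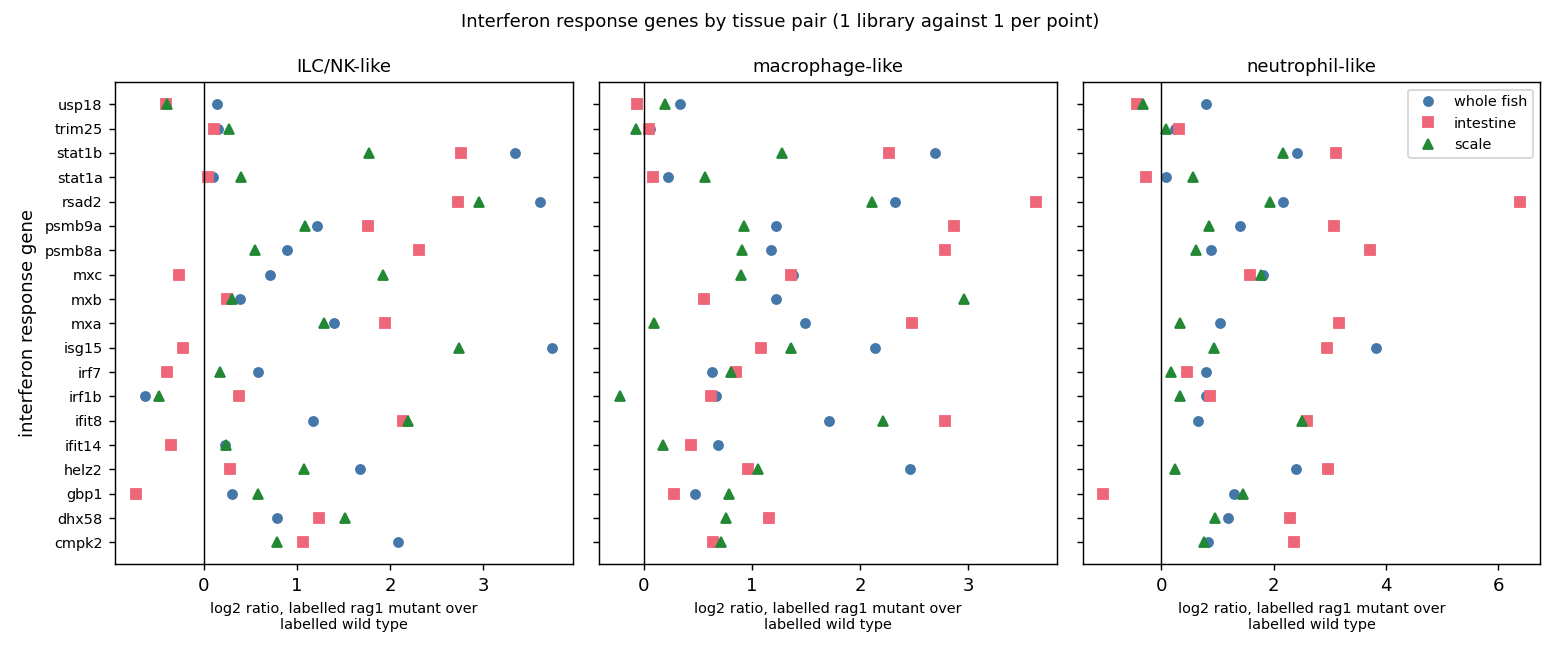
Log2 ratio of the library labelled rag1 mutant over the library labelled wild type (linear axis) for each interferon response gene in 3 cell classes; each point is 1 tissue pair and the line marks 0. stat1b and rsad2 lie above 0 in all 3 tissue pairs and classes, and isg15 lies below 0 in the intestine pair of ILC/NK-like cells.

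The interferon list kept its direction in the intestine pair as labelled, unlike the T- and B-like shares. Its median log2 ratio there was 0.29 in ILC/NK-like, 0.97 in macrophage-like and 2.36 in neutrophil-like cells, against 0.78, 1.18 and 1.05 in whole fish and 0.79, 0.81 and 0.76 in scale. Members above 0 in the intestine pair were 13 of 19, 18 of 19 and 14 of 17. These ratios had a constant added to CPM, which draws those of low genes towards 0. They are thus not on the scale of edgeR's log2 fold changes. Without the intestine pair, the list was still up at camera's preset correlation (median edgeR log2 fold change 1.19, 1.08 and 1.18, camera adjusted p = 1.1e-07, 5.3e-09 and 1.6e-08). This alternative was added after seeing the data, and no estimated correlation was run there.

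Proliferation genes were also placed higher in the libraries labelled rag1 mutant. In ILC/NK-like cells 20 of 21 members lay above 0 (median 0.69, camera adjusted p = 1.2e-09), and in macrophage-like cells 20 of 21 (median 0.48, camera adjusted p = 2.0e-07); neither held with an estimated correlation (adjusted p = 0.532 and 0.322 with an estimated correlation), and 0 members passed, also when adjusted over the list alone. By the tissue ratios, whole fish carried most of the size in ILC/NK-like cells, with a median log2 ratio of 1.16 against 0.23 in the intestine as labelled and 0.37 in scale. These ratios again had a constant added to CPM. The cycling marker mki67 was 24.5 and 60.2 CPM in ILC/NK-like cells of wild-type and mutant whole fish, 14.4 and 21.6 CPM in the intestine libraries and 26.3 and 40.8 CPM in scale. Oxidative phosphorylation genes were up in ILC/NK-like cells (median 0.26, camera adjusted p = 0.0040) and macrophage-like cells (median 0.52, camera adjusted p = 1.7e-05), and dissociation and heat stress genes were down (median -0.28 and -0.32, camera adjusted p = 0.0379 and 0.0110). The lower dissociation genes lay in the scale pair (median log2 ratio of CPM plus a constant -0.67 and -0.64). Without that pair the median edgeR log2 fold changes were -0.05 and -0.05 (camera adjusted p = 0.488 and 0.586). The oxidative phosphorylation call in ILC/NK-like cells was lost without the scale pair (median 0.19, camera adjusted p = 0.116). None of these 4 calls held with an estimated correlation (adjusted p = 0.532, 0.636, 0.532 and 0.636 with an estimated correlation). ILC1/NK genes were placed up in macrophage-like and neutrophil-like cells (median 0.74 and 0.58, camera adjusted p = 0.0395 and 0.0390; adjusted p = 0.636 and 0.634 with an estimated correlation), calls that were lost without the whole-fish pair (camera adjusted p = 0.710 and 0.449), and in neutrophil-like cells also without either other pair. The share of ILC/NK-like cells, which carry these genes, was also higher in mutant whole fish and scale (34.5% against 19.5% and 52.1% against 31.7%), and RNA from them was not tested as a source. The remaining lists did not pass, with camera adjusted p of 0.109 to 0.642 in ILC/NK-like, 0.222 to 0.993 in macrophage-like and 0.130 to 0.929 in neutrophil-like cells. Fits added after seeing the data moved some of these lists, at camera's preset correlation only, as no estimated correlation was run there. Without the intestine pair, V(D)J and T-lineage genes were placed down in ILC/NK-like cells (3 of 12 above 0, camera adjusted p = 0.0024) and macrophage-like cells (0 of 11, camera adjusted p = 3.7e-05). T-like cells were scarcer in the mutants of the same 2 tissues (15.8% against 24.0% and 0.326% against 4.76%), and RNA from them was not tested as a source either. Without the whole-fish pair, inflammatory and antibacterial genes were placed down in ILC/NK-like cells (camera adjusted p = 1.8e-04 and 4.3e-04). Adjusted over the list alone, 1 ILC1/NK member and 1 ambient epithelial member rose in ILC/NK-like cells, and 3 dissociation and heat stress members fell in neutrophil-like cells.

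No single gene passed edgeR's quasi-likelihood test for genotype. Of 19016 genes tested in ILC/NK-like cells 816 had an unadjusted p under 0.05, of 16795 in macrophage-like cells 1246, and of 12262 in neutrophil-like cells 659. The first count lay below a share of 0.05 and the others above it. In ILC/NK-like cells it was 2328 of 18224 without the intestine pair, 532 of 18231 without whole fish and 426 of 17965 without scale. Across genes, the intestine log2 ratios of this class as labelled ran against those of whole fish and scale (r = -0.24 and -0.20). The DESeq2 Wald test called 64 genes in ILC/NK-like cells (44 higher, 20 lower), 65 in macrophage-like cells (43 higher, 22 lower) and 39 in neutrophil-like cells (37 higher, 2 lower). Its calls included 11 interferon response members in at least 1 class, and 10 genes were called in all 3 classes. Of these 10, chosen for naming after their values were seen, stat1b had DESeq2 adjusted p of 8.3e-08, 8.4e-05 and 1.7e-07 and the interferon-induced gene ifi45 1.3e-04, 1.0e-04 and 6.0e-07. The immunoproteasome genes psmb9a and psmb12 were also among them. Without the filter on low counts, edgeR called 0, 5 and 158 genes in ILC/NK-like, macrophage-like and neutrophil-like cells. In neutrophil-like cells it called 8 genes without the intestine pair, nkl.1 and cfd among them, and 12 without the scale pair, rsad2, isg15, helz2 and stat1b among them; in ILC/NK-like cells it called 1, si:dkey-78l4.13, without the intestine pair.

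The second comparison set scale against intestine at the same age, with both genotypes, and asked how the tissue marks ILC/NK-like cells. In these cells edgeR called 737 of 19016 genes, 260 higher and 477 lower in scale, all in the same direction in both genotypes as labelled. The ILC2 genes were lower in scale: 4 of 8 fell and 0 rose (median -1.97, camera adjusted p = 0.0050; adjusted p = 0.840 with an estimated correlation). Adjusted over the list alone, 5 fell and 1 rose. il13 fell by 4.67 ± 0.37 (log2, SE; edgeR adjusted p = 0.00887), il4 by 3.35 ± 0.26 and the transcription factor gene gata3 by 3.47 ± 0.48, from 441 and 384 CPM in the intestine libraries to 75.0 and 22.7 CPM in scale. These genes were highest in L21, which held 633 and 307 cells of the intestine libraries and 0 of scale, with il13 at 6933 CPM there.

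Among the named genes lower in scale, epas1a (ENSDARG00000008697) encodes a hypoxia-inducible transcription factor. It was 881 and 646 CPM in the intestine libraries and 1.02 and 0.426 CPM in scale (log2 fold change -10.37 ± 0.41 SE, edgeR adjusted p = 0.00695). hic1, which encodes a transcriptional repressor, was 118 and 176 CPM against 0.0463 and 0.332 CPM (log2 fold change -9.62 ± 0.70, adjusted p = 0.00784). ahr2, the gene of an aryl hydrocarbon receptor and a member of the ILC3 list, fell by 2.28 ± 0.39 (log2, SE; adjusted p = 0.0407) and csf3a, a granulocyte growth factor gene, by 5.08 ± 0.26 (adjusted p = 0.00695). Pooled over the libraries of a tissue, spink2.2 was higher in the intestine by a ratio of 1294 (95% counting interval 232 to 51107, 1 UMI in scale), pku300 by 617 (111 to 24366, 1 UMI), ttpa, a tocopherol transfer protein gene, by 369 (102 to 3048, 2 UMIs) and the galectin gene lgals2b by 274 (75.8 to 2261, 2 UMIs). With no UMI in scale and the limit of 3 counts over the tissue, opn7d was at least 40.1-fold higher in the intestine, gpr132a at least 33.3-fold, vsig10l at least 25.7-fold, fabp6 at least 19.7-fold, ripply2 at least 18.5-fold and gpr37l1b at least 15.1-fold. Some of these genes mark other cells of the intestine libraries. spink2.2 was among the top 10 genes of unnamed C46 (90 and 192 intestine cells, 0 of scale) and lgals2b and fabp6 among those of epithelial-like C54 (33 and 115 intestine cells, 0 of scale). Free RNA from such cells was not tested for these genes.

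Epithelial genes led the genes higher in scale in ILC/NK-like cells. The keratin gene krt5 was 37.97 and 31.1 CPM in the scale libraries with no UMI in the intestine, at least 627-fold higher over 3 counts per tissue (edgeR adjusted p = 0.00887). krt91 was higher by a ratio of 429, cldnb by 327 (112 to 1588, 3 UMIs in the intestine) and icn2 by 340 (60.9 to 13410, 1 UMI). The claudin genes cldna and cldne were at least 77.3-fold and 38.8-fold higher, the aquaporin gene aqp3a at least 85.8-fold and the growth factor gene epgn at least 21.8-fold. krt5 had like levels in the other classes of the scale libraries, at 37.2 and 52.9 CPM in macrophage-like cells. Of the ambient epithelial list, 4 of 13 members rose and 1 fell (camera adjusted p = 0.00730; adjusted p = 0.840 with an estimated correlation), and adjusted over the list alone 6 rose and 2 fell. The chemokine gene cxcl18b was higher by a ratio of 354 (63.5 to 13967, 1 UMI in the intestine), the MHC class II gene mhc2dab at least 78.5-fold, fabp1b.2 at least 60.6-fold and the prostaglandin D synthase gene ptgdsb.1 by a ratio of 211. krt5, krt91, cldnb and icn2 were among the top 10 genes of epithelial-like C36 (391 and 437 scale cells), ptgdsb.1 among those of epithelial-like C48 (4 and 230) and cxcl18b among those of stromal-like C42 (181 and 222), each with 0 intestine cells.

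Other lists moved less in ILC/NK-like cells. Of the ILC1/NK genes, 3 of 17 fell in scale and 0 rose: nkl.4 by 3.68 ± 0.23, eomesa, a T-box factor gene of NK cells, by 2.1 ± 0.31 and nkl.3 by 1.73 ± 0.27 (log2, SE). Adjusted over the list alone, 5 fell and 2 rose. The camera test of this list did not pass (adjusted p = 0.492), nor did that of any list except the ILC2 and ambient epithelial ones (adjusted p of 0.0856 to 0.727). stat1b was the 1 of 19 interferon members that rose (log2 fold change 3.13 ± 0.53 SE, edgeR adjusted p = 0.0394). Of 20 inflammatory members cxcl18b rose and csf3a and ccl20a.3 fell, of 9 MHC class II members mhc2dab rose, and of 12 antibacterial members mmp9, a matrix metalloproteinase gene, rose. Adjusted over the list alone, 4 inflammatory members rose and 5 fell, 2 MHC class II members rose, and 1 antibacterial member rose and 2 fell. The count of called genes was 382 in the 4 adult libraries alone, 1433 without the intestine library labelled rag1 mutant and 2048 without the one labelled wild type, the last 2 added after seeing the data. DESeq2 called 2067 genes, and edgeR without a filter on low counts called 1160.

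Macrophage-like cells also differed between scale and intestine, with 1315 of 16795 genes called, 690 higher and 625 lower in scale. They also lay mostly in different clusters, C19 in the intestine and C3 in scale. As in ILC/NK-like cells, epas1a was lower in scale, at 231 and 285 CPM in the intestine libraries and 0.886 and 0.592 CPM in scale (log2 fold change -8.49 ± 0.37 SE, edgeR adjusted p = 0.00794), and so was hic1 (log2 fold change -7.61 ± 0.43, adjusted p = 0.00990). The retinol-binding protein gene rbp2a was 386 and 667 CPM in the intestine libraries and 6.21 and 0.921 CPM in scale (log2 fold change -7.42 ± 0.94, adjusted p = 0.0225). The intelectin gene itln1 was higher in the intestine by a ratio of 152 (52.1 to 738, 3 UMIs in scale), spink2.2 by 251 (86.0 to 1219, 3 UMIs), the complement gene c3a.4 by 164, TENM2_037122 by 95.6 and the sodium-calcium exchanger gene slc8a4b by 89.98. tm4sf4 was at least 31.6-fold higher in the intestine, ripply2 at least 28.1-fold, the proenkephalin gene penka at least 19.1-fold and DRD5 at least 15.5-fold. Here too, some genes mark other cells. itln1 and c3a.4 were among the top 10 genes of unnamed C11 (1072 and 471 intestine cells, 2 and 2 of scale), spink2.2 of C46, tm4sf4 of C54, TENM2_037122 of progenitor-like C22 (279 and 116 intestine cells, 26 and 68 of scale), and epas1a of ILC/NK-like L8 and L14. Free RNA from such cells was not tested for these genes.

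In scale, macrophage-like cells were higher in lmna, the gene of nuclear lamin A, by a ratio of 622 (213 to 3018, 3 UMIs in the intestine), with 107 and 132 CPM in the scale libraries. The transcription regulator id4 was at least 161-fold higher, the gap junction gene cx35.4 at least 41.7-fold, the integrin gene itgb3b at least 43.7-fold, the nitric oxide synthase gene nos2b at least 32.4-fold, tdp2a at least 38.5-fold and rnd1b at least 31.8-fold. Epithelial genes were again among the largest rises, with krt5 at least 235-fold, krt91 at least 208-fold, aqp3a at least 112-fold, icn2 at least 44.7-fold and cldna at least 25.5-fold higher. Of the ambient epithelial list, 4 of 8 members rose (camera adjusted p = 0.00187; adjusted p = 0.416 with an estimated correlation), and adjusted over the list alone 5 rose and 1 fell.

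Cell cycle genes were lower in scale macrophage-like cells. Of 21 proliferation members, 5 fell and 0 rose over all genes tested, and 18 fell adjusted over the list alone (median -1.23, camera adjusted p = 9.6e-08; adjusted p = 0.295 with an estimated correlation). mki67 was 22.0 and 33.2 CPM in the intestine libraries and 8.14 and 13.9 CPM in scale, and the replication gene mcm2 fell by 1.79 ± 0.28 (log2, SE; edgeR adjusted p = 0.0325). Of 22 dissociation and heat stress members 1 fell, junbb, and 12 fell adjusted over the list alone (median -0.98, camera adjusted p = 4.3e-05; adjusted p = 0.416 with an estimated correlation); scale had been digested for 30 minutes and intestine for 20. Interferon response members were up in scale (median 1.16, camera adjusted p = 8.0e-04; adjusted p = 0.416 with an estimated correlation), with isg15 and mxc rising among 19, and oxidative phosphorylation members were down (median -0.54, camera adjusted p = 0.0206; adjusted p = 0.666 with an estimated correlation). Of the MHC class II list 1 of 9 rose, mhc2dab, and of the inflammatory list 2 of 20, cxcl18b and nos2b. Single members passed in the ILC1/NK (prf1.9, lower), ILC2 (il13, lower), ILC3 (rorca, higher), antibacterial (mpx, higher) and V(D)J and T-lineage lists (cd4-1, higher). Adjusted over the list alone, 2 ILC2 members fell, and 2 ILC3 and 3 inflammatory members rose. The remaining lists did not pass (camera adjusted p of 0.0640 to 0.751). The count of called genes was 254 in the 4 adult libraries alone, 739 without the intestine library labelled rag1 mutant and 556 without the one labelled wild type; DESeq2 called 2472 and edgeR without a filter on low counts 2425.

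The last comparison concerned leukocytes that the design text describes as independent of haematopoietic stem cells, labelled PBI-derived, at 2 weeks of age. They held ILC/NK-like cells but few B-like cells. ILC/NK-like cells were 32.1% of the library (31.2 to 33) against 19.5% of wild-type whole fish at 1 month, B-like cells were 0.0582% against 4.00%, and T-like cells were 8.23% against 24.0%. The log2 ratios were 0.72, -5.99 and -1.54, with no test because each side was 1 library. At 0.5 times the clustering resolution the ILC/NK-like ratio was 0.02. With L2 and L3 counted as T-like, the T-like shares were 8.32% against 52.3% and the ratio was -2.65. Unnamed cells were another 28.9% against 35.3%, and 2289 of the 2978 PBI-derived ones lay in lymphoid sub-cluster L4. The named shares leave these cells out. Age and reporter differed along with origin, and the median depth was 3293 UMIs per cell against 5220.

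The T-like cells of the PBI-derived library were mostly L25 (87.4%), with rag1 at 2210 CPM, lck at 1234 CPM and cd4-1 at 316 CPM in that sub-cluster but cd8a at 1.13 CPM (2 UMIs) and cd28 at 3.39 CPM. Of these genes, rag1, cd4-1, cd8a and cd28 were among the markers used to name T-like clusters. Within ILC/NK-like cells, sub-clusters led by the ILC2 genes held 14.2% of cells in the PBI-derived library and 6.74% in wild-type whole fish, while those led by the ILC1/NK genes held 0.241% and 11.1%. The main sub-clusters were L24, L30 and L20 in the former and L7 and L10 in the latter.

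Genes of these ILC/NK-like cells were compared between the pair of libraries without a test. Higher in the PBI-derived library were cyp1a, a target of the aryl hydrocarbon receptor (104 against 0.567 CPM), the cathepsin gene ctss1 (185 against 17.1 CPM), faslg, which encodes Fas ligand (105 against 13.5 CPM), and il12bb (58.6 against 5.04 CPM), along with cst14b.2, mafbb, hist1h4l_105409, marcksl1b, sult6b1, ncf1, inhbb and kalrnb. Of these, sult6b1 was among the top 10 genes of neutrophil-like C15 (1772 PBI-derived cells against 3), cst14b.2 of unnamed C47 (173 against 30), hist1h4l_105409 of unnamed C28 (342 against 132) and il12bb of macrophage-like C23 (115 against 156). Lower were nkl.1 (94.0 against 799 CPM), tcf7, a lymphoid transcription factor gene (106 against 1143 CPM), the MHC genes mhc1uba (2.35 against 253 CPM), b2m (72.1 against 639 CPM), mhc2a and mhc2b, and EGFP, znf1096, rbfox3a, creb5b, cacna1g and gpc5a. EGFP stood at 195 against 1608 CPM. tcf7 was also among the top 10 genes of T-like L12 (19 against 1362 cells). Proliferation genes had a median log2 ratio of 1.16, above 100% of matched random lists, oxidative phosphorylation genes 0.80 (above 100%), antibacterial genes 0.63 (above 100%) and inflammatory genes 0.21 (above 99.9%). ILC1/NK genes had a median of -0.77 (above 0%), V(D)J and T-lineage genes -0.52 (above 0.02%), MHC class II genes -0.88 (above 0.2%) and interferon genes -0.35 (above 0.7%). ILC2 genes (-0.01), ILC3 genes (-0.08) and dissociation genes (-0.09) lay between the 48.6 and 64.9 percentiles, and ambient epithelial genes (0.21) above 99.99%. Neutrophil-like cells were 18.5% of the PBI-derived library against 5.41% of wild-type whole fish, and T-like cells 8.23% against 24.0%, so antibacterial and T-lineage genes moved with the cells that carry them; free RNA was not tested here.

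Macrophage-like cells of the PBI-derived library (mainly C33) were higher in ctsl.1, a cathepsin gene (1364 against 25.9 CPM), the macrophage marker mfap4 (1874 against 263 CPM), mhc2dab (174 against 1.25 CPM) and the chemokine gene ccl20a.3 (184 against 3.13 CPM), as well as in cldni, sult6b1, mxf, spink2.4, ccl38.6, rbm24a, rrad and myo3a. sult6b1 again marked C15 and spink2.4 C47, and ccl20a.3 was among the top 10 genes of ILC/NK-like L24 (560 PBI-derived cells against 54). They were lower in the MHC class II genes cd74a (862 against 10919 CPM), mhc2a (396 against 3493 CPM) and mhc2b, in the apolipoprotein gene apoeb (65.2 against 1124 CPM), and in g0s2, mhc1uba, gpc1b, cadm4, znf1096, EGFP, jdp2b and il4r.1. Proliferation genes had a median log2 ratio of 0.54 (above 100% of matched random lists) and V(D)J and T-lineage genes of -0.46 (above 0.01%). Antibacterial genes (0.74), oxidative phosphorylation (0.50), ambient epithelial (0.19), inflammatory (0.32) and interferon genes (0.17) lay at or above the 97.1 percentile. Dissociation genes (-0.44) and MHC class II genes (-0.53) lay at the 0.79 and 2.42 percentiles, and ILC1/NK (0.01), ILC2 (0.10) and ILC3 genes (-0.01) between 57.3 and 86.9.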

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

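The tests of carry-over and exchanged labels were chosen after the shares had been seen.

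T-like and B-like shares differed in opposite directions in the intestine and in the other tissues. The log2 ratio of rag1 mutant over wild type was 5.54 for T-like cells in the intestine as labelled against -0.61 in whole fish and -3.85 in scale, 6.44 for B-like cells against -7.14 and -7.17, and -0.32 for ILC/NK-like cells against 0.82 and 0.72. The ILC/NK-like sign in the intestine was not stable: the ratio was -1.34 at 0.5 times and 0.014 at 2 times the resolution, -0.38 with 4000 variable genes, 0.10 with doublets kept and 0.15 at 500 genes. The difference between tissues was not tested, since each tissue had 1 library per genotype.

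Carry-over from the intestine library labelled wild type is argued against, as its T-like share was 0.389%, far below the 18.4% of the library labelled rag1 mutant. The make-up of the latter's T-like cells by sub-cluster overlapped with that of wild-type whole fish or scale by at most 8.47%. This cannot decide on carry-over from those libraries, because libraries were not integrated and T-like sub-clusters lay mostly in 1 library each. L12 held 1362 cells of wild-type whole fish and 15 of wild-type scale, and L33 held 7 and 509. An exchange of the 2 intestine labels may account for the shares, as both libraries are out of place. With exchanged labels, 2 of 6 correlations across genes between the intestine ratios and those of whole fish or scale exceeded 0.1, both in ILC/NK-like cells (0.24 and 0.20), while macrophage-like (-0.13 and 0.08) and neutrophil-like cells (-0.09 and 0.04) gave none; genes are not independent replicates. The interferon response, by contrast, lay with the labels as given in macrophage-like (18 of 19 members above 0) and neutrophil-like cells (14 of 17). In ILC/NK-like cells it did so less clearly (13 of 19 members, median log2 ratio 0.29). An exchange and a tissue-specific difference between the pools thus cannot be told apart.

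DsRedx, the reporter that recombination removes in the transgene of the PBI-derived fish, stood at 11.1 CPM in the PBI-derived library and 0.426 CPM in mutant whole fish, above what a count of 0 allows. NTRO, an added feature with no description in the labels, stood at 1.39 CPM in wild-type scale, 0.970 CPM in mutant whole fish and 0.919 CPM in mutant scale, above what a count of 0 allows.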

How the results depend on the processing

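Leaving out either intestine library, the wider T-like class and the 12 gene lists without a tissue pair were alternatives chosen after seeing the data. For genotype, where edgeR called 0 genes in each class, DESeq2 called 64, 65 and 39 genes in ILC/NK-like, macrophage-like and neutrophil-like cells, no filter on low counts gave 5 in macrophage-like and 158 in neutrophil-like cells, and leaving out 1 tissue pair gave 0 to 1 in ILC/NK-like and 0 to 12 in neutrophil-like cells; the cause was not tested. Other size factors, kept doublets and no tissue block gave 0 in each class. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05; all 10 gave as many genes as the real split, with 0 genes in it and at most 0 in the others, in each class. For scale against intestine, the 737 genes of ILC/NK-like cells became 2067 with DESeq2, 1160 without a filter, 382 in the 4 adult libraries, and 1433 or 2048 without the intestine library labelled rag1 mutant or wild type. The 1315 genes of macrophage-like cells became 2472, 2425, 254, 739 and 556 in the same order; the cause was not tested, except that the last 3 use fewer libraries. The T-like mean log2 ratio of 0.36 turned to -1.14 with doublets kept, -0.10 with 4000 variable genes, -0.0172 with L2 and L3 counted, and ranged from -2.23 to 2.47 with 1 tissue pair left out; B-like and ILC/NK-like means kept their sign but not their size. The B-like mean of -2.62 was -1.08 with doublets kept, where the whole-fish ratio of -7.14 became -2.80, and -7.15 to -0.35 with 1 pair left out. The ILC/NK-like mean of 0.41 was 0.05 at 0.5 times the resolution and 0.57 at 500 genes, and 0.20 to 0.77 with 1 pair left out. For the PBI-derived library the T-like ratio of -1.54 moved to -1.81 at 500 genes and -2.65 with L2 and L3 counted, and the ILC/NK-like ratio of 0.72 to 0.0176 at 0.5 times and 0.52 at 2 times the resolution, 0.45 with doublets kept and 0.53 with 4000 variable genes; the cause was not tested. Of 11 list calls for genotype, 5 were lost with at least 1 tissue pair left out, 6 held in each such fit, and 9 other lists were called in at least 1. With 1 tissue pair left out, the median of V(D)J and T-lineage genes, -0.33 in macrophage-like cells, became -0.86 without intestine and 0.0661 without scale, and in ILC/NK-like cells -0.29 became -0.73 without intestine. In ILC/NK-like cells the inflammatory median of -0.06 became -0.61, 0.13 and 0.0213, and the antibacterial median of -0.18 became -0.79, 0.51 and -0.18, without whole fish, intestine and scale; the cause was not tested. Of 48 named tissue results none reversed, 33 passed in all 5 alternatives run for single genes that could test them, and 34 passed in the 4 adult libraries alone. The genotype test, with 2 residual degrees of freedom, recovered 6.12% of simulated 2-fold changes in ILC/NK-like cells.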

Other observations

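Several leukocyte classes not compared above differed between tissues. Metaphocyte-like cells, epidermal myeloid-like cells, made up 4.31% of wild-type and 2.36% of mutant scale cells, 0.333% and 0.833% in whole fish, and 0 of 10275 and 0 of 7904 cells in the intestine libraries labelled wild type and rag1 mutant, which allows up to 0.0292% and 0.0380%. Macrophage-like cells were 8.73% and 17.3% in wild-type and mutant whole fish, 18.0% and 24.4% in scale, and 15.8% and 6.98% in the intestine as labelled. Neutrophil-like cells were 18.5% of the PBI-derived library and 2.25% to 11.3% elsewhere. Thrombocyte-like cells were 1.08% of the intestine library labelled rag1 mutant. None of these differences was tested.

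B-like cells of wild-type scale (72 cells, 3 months) and wild-type whole fish (444 cells, 1 month) differed in some genes. Age and pool differed along with site, and no test was made. B-like cells of wild-type scale held the immunoglobulin light gene igic1s1 at 10139 CPM and ighz, the heavy constant gene of a fish immunoglobulin class, at 528 CPM, against 603 and 174 CPM in wild-type whole fish, whereas pax5, a B-lineage transcription factor gene, was 453 and 588 CPM. An unnamed sub-cluster of whole fish, L31, held rag1 at 4806 CPM and dntt at 3021 CPM in 137 wild-type cells, and at 3467 and 2630 CPM in 404 mutant cells, with lck at 78.0 and 23.7 CPM. It made up 1.23% of wild-type and 2.55% of mutant whole-fish cells. In the T-like cells of the intestine library labelled rag1 mutant, foxp3a was 42.7 CPM and foxp3b 54.4 CPM, against 0.740 and 81.7 CPM in those of wild-type scale.

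The tests of cluster make-up, of free RNA for the interferon genes and of pools below were set before their values had been seen, and all others after. The make-up test of ILC/NK-like cells was added once that of the other 2 classes had been seen. 2 earlier measures of free RNA for these genes were replaced after they were seen: the median ratio of the largest over the smallest class level (2.22), and the share of rises that depart from 1 ratio between classes (54.5%), which set differences between libraries against counting error alone. icn was split from the other epithelial genes after a first look at class levels and shared droplets.

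Interferon response genes were higher in the libraries labelled rag1 mutant in all 3 innate classes. At camera's preset correlation a single tissue does not carry this, as the largest adjusted p over the classes with any 1 tissue left out was 1.1e-07; with an estimated correlation the list did not pass even with all 3 tissues (adjusted p = 0.532, 0.335 and 0.634). Within C13 of neutrophil-like and C23 of macrophage-like cells, the lowest median log2 ratio of any tissue was 0.50. This argues against a shift between clusters as the whole cause only for the cells of those clusters. C13 held 18.0% of neutrophil-like cells in each whole-fish library, and 69.9% to 91.5% in the intestine and scale libraries. C23 held 261 of 2742 macrophage-like cells in mutant whole fish and 236 of 2998 in mutant scale. In the intestine libraries labelled wild type and rag1 mutant it held 10.1% and 24.1%. Other clusters of these classes were not tested. In ILC/NK-like cells a shift is argued against only for the sub-clusters that both libraries of a tissue shared. There, the same sub-cluster make-up in both kept at least 0.607 times the list's median log2 ratio (0.89 became 0.54 in scale). In scale these sub-clusters held 77.7% of mutant and 92.0% of wild-type ILC/NK-like cells. L16, with 1259 mutant and 12 wild-type scale cells, lay outside them, so a shift into it was not tested. Free RNA in the mutant libraries stays open. The lowest UMIs per cell of any cluster were taken off each member in the mutant alone. With 5 added to CPM, the median log2 ratio went from 0.59 to 0.27, 0.88 to 0.64 and 1.18 to 0.80 in ILC/NK-, macrophage- and neutrophil-like cells. The lower limits over members were -0.121, -0.0720 and 0.0340. With this constant, the ratios are not on the scale of edgeR's log2 fold changes. A raised interferon response in rag1 mutants, or a difference in exposure between pools of fish, may underlie the higher levels. These explanations cannot be told apart, because each tissue had 1 pool per genotype. The exact sign-flip test over 3 tissues also allows no p below 0.25.

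Epithelial genes were higher in scale than in intestine in ILC/NK-like and macrophage-like cells. For krt4, krt5, krt17 and icn2, free RNA of epithelial cells in the scale libraries stays open: the largest class level was a median of 1.64 times the smallest over ILC/NK-, macrophage- and neutrophil-like cells, but krt4 reached 2.95 in mutant scale and krt17 2.38 in wild-type scale, where free RNA would keep each under 2. A shared droplet with an epithelial cell is argued against, as the 1% of ILC/NK-like cells with most of these UMIs held 14.0% of them. For icn, which reached 2952 CPM in ILC/NK-like cells of mutant scale, free RNA is argued against, since its level differed at least 4.41-fold between classes in each scale library. A look at these same levels had led to icn being split off, so the test was not independent of that choice. Whether ILC/NK-like cells of scale express icn themselves remains a hypothesis.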
